A study of Homo sapiens with 18 samples.

How the data were processed

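RNA was measured by RNA-seq in 18 libraries: 12 from the K-562 cell line, 3 from FFPE kidney and 3 from pancreas. Each library formed its own group, named by RNA, method, input and whether the RNA was fragmented. K-562 and its methods were read from the sample labels. The 6 tissue libraries were assigned from the column names of the deposited tables, and the marker genes were checked: the loop of Henle list summed to 1362 to 1562 TPM in the kidney libraries and 59.0 to 80.5 in pancreas. "NS" in 1 RNase H library is not explained by the labels.

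Per the labels, the authors used BWA 0.6.1, SAMtools 0.1.9, Picard (no version given), Bowtie 0.12.7 and RSEM 1.1.17, without saying which step each served. Features are UCSC known gene clusters, and the genome build is not given, so no coordinates were used. The series tables hold TPM values, deposited by the authors as RSEM estimates for all 18 libraries, with genes and isoforms apart. For 11 K-562 libraries the authors also deposited expected counts, the RSEM estimate of reads per gene, of which some are not whole because shared reads are split. The same deposited files hold a fraction, the RSEM share of transcripts per gene, which times 1000000 equals the TPM of the series table.

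The tables held 31227 clusters and 80922 isoforms. Clusters with the same symbol were summed (1298 symbols had more than 1), leaving 26597 symbols. Neighbouring genes merged in 1 cluster stay merged, and near-identical copies such as histone genes, HBA1 and HBA2, or trypsinogens share reads. Transcript length and GC content were those of the longest basic transcript of each gene in GENCODE release 29. They were found for 20920 symbols (78.7%).

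In each pair, genes with a mean TPM of at least 1 were tested, and the log2 ratio of TPM plus 1 was taken. A gene was counted as beyond 4-fold at a ratio of 2 or more either way. Counts are given as TPM is scaled, and again relative to the median tested gene. Gene and list ratios are given relative to the median gene. The plan had TPM as scaled for these and centring as the alternative; the order was turned round after the data were seen, because the short RNAs that take much of the TPM shift all other genes, and the rank of a list among random lists is the same either way.

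Because there are no replicates within an RNA, no difference between libraries was tested and no p-value is given. Where expected counts exist, a 95% exact binomial interval on the counts of both libraries was turned into an interval on the ratio, without the pseudocount. It covers counting error only. Gene lists (28 of them) were fixed before the data were examined, as were the comparisons (12 main and 7 secondary), the filters and the rule for naming genes. A list needed at least 3 members measured. Its median was ranked among 10000 random lists of the same size drawn from 20 bins of mean expression, and it was said to stand apart outside the central 95%. This describes the libraries in hand. Cytoplasmic ribosomal RNA, mitochondrial mRNA and mitochondrial ribosomal RNA had at most 1 member in the tables and were not ranked.

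The main reference was Total for the methods at 1000 or 100 ng and for the tissues, and PolyA for the 1 ng libraries on intact RNA. Named genes were the 5 highest and 5 lowest ratios among genes with a mean TPM of at least 10, plus up to 4 members of each list with the largest ratios (3, 3 and 2 in secondary pairs), with ABL1, BCR, GATA1, ACTB and GAPDH as reference points. From these the text names genes of known function. Left out of naming were 137 symbols: genes on the sex chromosomes that mark sex, HLA genes, immunoglobulin and T cell receptor segments, and genes often deleted in healthy people, because they can vary between people. These symbols were also left out of the gene lists and of the tested genes, and so of the median gene, the 4-fold counts and the correlations. In the tissue pairs a few developmentally regulated genes were left out of the tested genes as well. Further measures were Spearman correlation across genes, genes detected at a TPM of 1, classes of GC content, length and abundance with at least 20 genes each, and the most abundant isoform of each gene. Genes are not independent replicates, so correlations describe libraries.

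Depth was 10007074 to 10122517 expected counts in 10 libraries and 6010007 in NuGEN 1 ng fragmented. The TPM that 3 counts give for a gene of median length was 0.137 to 0.340. Depth is unknown for SMART and the tissues, so a value of 0 there has no floor. Libraries were thinned to equal counts for 1 measure of detection.

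The pipeline was tested on simulated data: drawn counts stood in for RNase H and Total, with planted changes in 200 of 11865 genes. Beyond 4-fold were 0% of genes planted at 2-fold, 94% of those at 6-fold and 100% of those at 10-fold and 20-fold. These shares hold for the planted genes only. The pseudocount damps the ratios of weak genes, so the shares do not carry over to all tested genes. Of 11665 genes without a planted change 9 were beyond 4-fold, none with 20 or more expected counts, and 7 of 200 random lists of 25 genes (3.5%) stood apart.

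Alternatives were a pseudocount of 0.1 or 5 TPM, no filter or a mean TPM of at least 10, centring, expected counts scaled to the library total, equal depth, leaving out small and mitochondrial RNAs, the mean of list members, a TPM of 5 for detection and 20 for isoforms, and a second seed. After the data were seen, 3 were added: clusters kept apart, and members or genes with at least 20 expected counts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Sequence reads were not analysed here, so alignment was not repeated.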

Results

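The series set library methods for scarce or degraded human RNA side by side on the same RNA. RNA-seq libraries were made from 3 RNAs: 12 libraries from the chronic myeloid leukaemia cell line K-562, 3 from a formalin-fixed, paraffin-embedded (FFPE) kidney, and 3 from a partially degraded pancreas RNA. Each group held 1 library and no difference was tested, so none has a p-value. Total, RNase H and Ribo-Zero were run on all 3 RNAs, and there only the directions were compared. RNase H and Ribo-Zero remove ribosomal RNA with probes, and DSN-lite digests the most abundant sequences of a finished library with a duplex-specific nuclease. NuGEN (the Ovation kit) and SMART (the SMARTer kit) amplify cDNA from small inputs. PolyA was selected with oligo(dT) beads, TruSeq is the Illumina kit, used here on 1 ng, and Total was made from total RNA. RNA was fragmented before DSN-lite, RNase H, Ribo-Zero and Total, and in the NuGEN libraries labelled fragmented. It was left intact for PolyA, TruSeq, SMART and NuGEN 1 ng intact. Inputs of total RNA were 1000 ng except for NuGEN 100 ng fragmented (100 ng) and the libraries labelled 1 ng; for PolyA the labels also give 10 ng of poly(A) RNA.

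The K-562 libraries held between 10007074 and 10122517 expected counts in genes, except NuGEN 1 ng fragmented with 6010007. SMART and the 6 tissue libraries came as TPM (transcripts per 1000000) only, so their depth is unknown and their values carry no interval. Ratios below are log2 ratios of TPM plus 1, relative to the median tested gene of the pair unless said otherwise. Brackets hold 95% counting intervals, computed without the added 1. They are centred on the ratio of TPM, which for short RNAs can differ from the ratio of the counts. The intervals cover counting error only. Scaled expected counts are expected counts divided by the library total, an alternative unit. A gene list stands apart when its median lay outside the central 95% of 10000 random lists of the same size and expression. This describes these libraries and is no test of the methods. The random lists were not matched on GC content or length, so a list can stand apart through these.

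**Figure D1:**
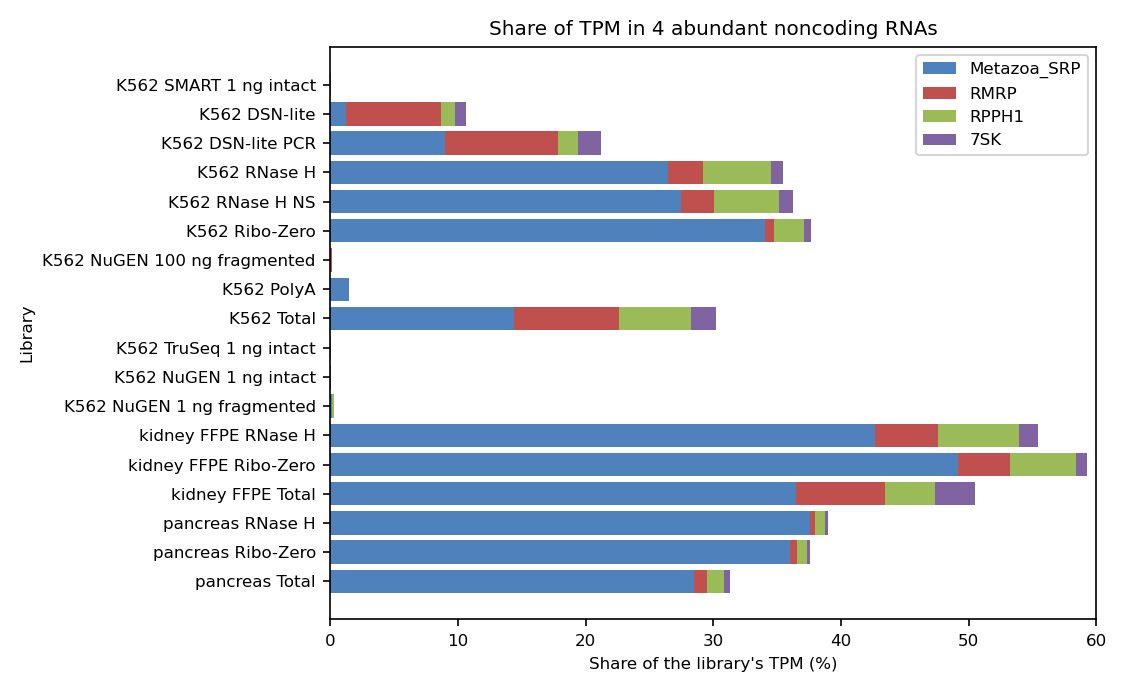
Share of each library's TPM (%) in 4 abundant noncoding RNAs, 1 bar per library. Metazoa_SRP, the RNA of the signal recognition particle, took 14.4% in K-562 Total, 1.44% in PolyA and 49.2% in kidney Ribo-Zero.

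A few short noncoding RNAs took much of the TPM wherever no poly(A) selection or cDNA amplification was used. Metazoa_SRP, the RNA of the signal recognition particle that guides secreted proteins to the membrane, took 14.4% of TPM in K-562 Total, 26.5% in RNase H and 34.1% in Ribo-Zero. It took only 1.19% in DSN-lite and 1.44% in PolyA. RMRP, the RNA of the RNase MRP enzyme, took 8.26% in Total, 2.68% in RNase H and 0.642% in Ribo-Zero. In the kidney libraries Metazoa_SRP took 36.5% (Total), 42.7% (RNase H) and 49.2% (Ribo-Zero), and in the pancreas libraries 28.5%, 37.6% and 36.0%. Short RNAs with few counts get high TPM because TPM divides by length, so these shares are shares of molecules as modelled and not of reads.

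**Figure D2:**
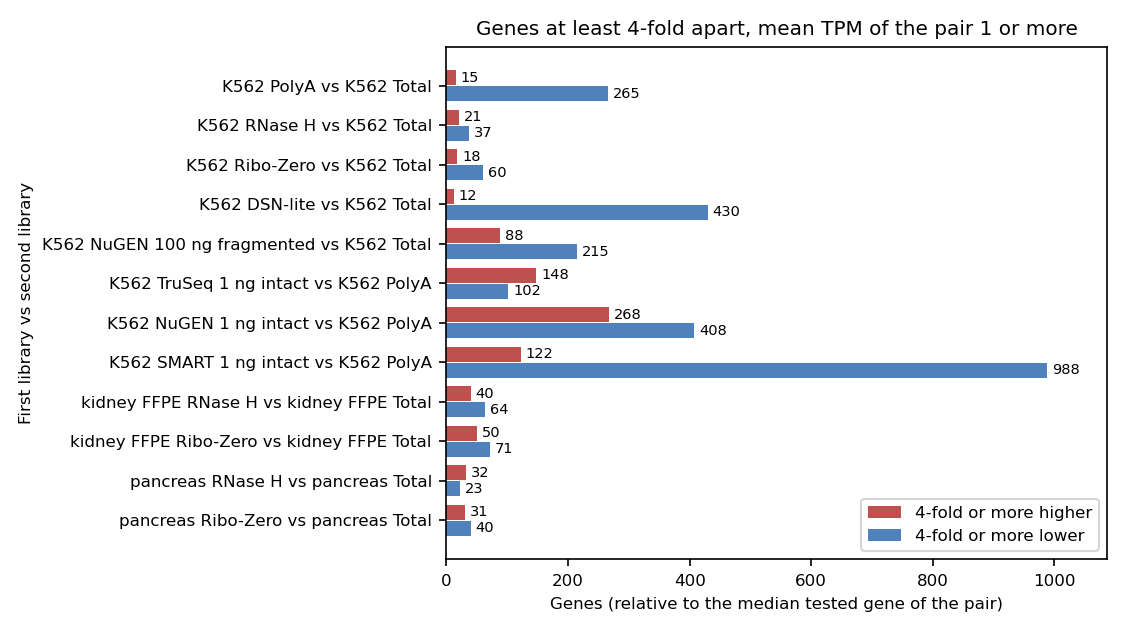
Number of genes at least 4-fold higher (upper bars) or lower (lower bars) than in the reference library, relative to the median tested gene, for the 12 main comparisons. SMART had the most genes 4-fold lower (988), and the RNase H and Ribo-Zero comparisons had at most 71.

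PolyA against Total compares poly(A) selection from intact K-562 RNA with fragmented total RNA. Effects of selection and of fragmentation cannot be told apart in this pair. RNAs without a poly(A) tail were nearly lost. The replication-dependent histone mRNAs, which end in a stem-loop and package new DNA, were lower for all 49 members, with a median of -5.09 (34.1-fold lower) and 44 members beyond 4-fold. HIST1H1B, a linker histone, had 6 counts against 1796. Guides for RNA modification, the snoRNAs and scaRNAs, had a median of -5.70 with 61 of 63 members lower, and the small structured RNAs a median of -8.34 with 5 of 6 lower. RMRP was at -10.90 (37 counts against 50407 [-11.44 to -10.47]), 7SK, a brake on transcription elongation, at -9.63 [-10.28 to -9.14], and RPPH1, the RNA of RNase P, at -9.41 [-9.71 to -9.16]. The polyadenylated histone variants were above the median gene in 7 of 7 members (median 0.48), which did not stand apart.

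Among the other lists, PolyA held less of very long mRNAs and nuclear long noncoding RNAs. Whether the latter carry a poly(A) tail was not checked. All 31 very long mRNAs were lower (median -1.09, 2.13-fold), among them MDN1, an ATPase of ribosome assembly (-1.76 [-1.88 to -1.74]), and BIRC6, an inhibitor of apoptosis (-1.87 [-2.03 to -1.85]). The 6 nuclear long noncoding RNAs were lower too (median -1.01), such as the paraspeckle scaffold NEAT1 (-1.19 [-1.24 to -1.17]). Nuclear OXPHOS subunits, of the respiratory chain, were higher in 36 of 41 members (median 0.63), with NDUFB2 at 1.42 [1.26 to 1.60]. Immediate early genes were higher in 13 of 15 (median 0.58), with JUND, an AP-1 transcription factor, at 1.06 [0.94 to 1.22]. Cytoplasmic ribosomal proteins (median 0.41, 68 of 76 above) did not stand apart from other abundant genes. Of 11928 genes, 33 were 4-fold higher and 195 lower in PolyA as scaled, and 15 and 265 relative to the median gene, which lay at 0.32. The snoRNA median was -8.61 with a pseudocount of 0.1 TPM and -2.62 in scaled expected counts, over 24 members.

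RNase H against Total asks whether removing ribosomal RNA with RNase H leaves the rest of the transcriptome as it was. It left most K-562 mRNAs close to Total: 21 of 11987 genes were 4-fold higher and 37 lower, and rho across genes was 0.981. Lower values were found for snoRNAs and scaRNAs, with a median of -1.96, 33 of 71 members 4-fold lower and 8 4-fold higher. Many of these had few counts, and the median was -0.60 over the 29 members with at least 20 counts and -0.12 in scaled expected counts. Among immediate early genes 13 of 15 were higher (median 0.19), with JUND at 0.57 [0.44 to 0.73]. Cytoplasmic ribosomal proteins were lower in 52 of 76 (median -0.21), with RPS27 at -1.64 [-1.74 to -1.53] and RPL37 at -1.14 [-1.20 to -1.09]. Histone mRNAs had a median of -0.15 and members on both sides, such as HIST1H2BD (-1.37 [-1.45 to -1.29]) and HIST1H4A (1.30 [1.02 to 1.60]).

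Of single RNAs, the entry MIR3648 (180 nt, 83.9% GC) was 44.4-fold higher in TPM after RNase H (5.47 [4.81 to 6.28]). Its counts give a larger fold (1393 against 17). Whether these reads come from the microRNA was not checked. RMRP was at -1.60 [-1.62 to -1.58] and 7SK at -1.04 (11003 counts against 17820). Small structured RNAs as a list had a median of -0.06, and NEAT1 lay at 0.06. The list calls are fragile: with the mean of the members in place of the median, the ribosomal proteins and the histone mRNAs no longer stood apart, and in scaled expected counts the histone median was 0.01.

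Ribo-Zero against Total addresses the same question for the probe capture kit. It also stayed close to Total in K-562 (18 of 11945 genes 4-fold higher, 60 lower, rho 0.977). Some abundant coding RNAs were lower in Ribo-Zero. MTND5, a mitochondrial mRNA for a subunit of complex I, was 6.17-fold lower (5456 counts against 32274; -2.63 [-2.67 to -2.59]). The alpha-like globins HBA1 (-1.98 [-2.06 to -1.90]), HBZ (-1.84 [-1.93 to -1.76]) and HBA2 (-1.76 [-1.90 to -1.64]), which carry oxygen in red cells, and the small heat shock protein HSPB1 (-1.58 [-1.74 to -1.44]) were lower as well, though the list of erythroid and globin genes as a whole had a median of -0.06. Cytoplasmic ribosomal proteins were lower in 60 of 76 members (median -0.23), with RPL28 at -1.35 [-1.43 to -1.28] and RPS16 at -1.33 [-1.40 to -1.25].

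The noncoding RNAs of the same comparison moved further apart. RMRP was 12.8-fold lower (-3.67 [-3.72 to -3.63]) and 7SK at -1.80 [-1.84 to -1.76], while SCARNA2, a guide RNA of the Cajal body, was 3.27-fold higher (16624 counts against 4579). The snoRNA and scaRNA median was -2.57 with 44 of 73 members 4-fold lower, and -1.52 over the 26 members with at least 20 counts (-0.95 in scaled expected counts). Histone mRNAs had a median of -0.35 (34 of 49 lower), nuclear OXPHOS subunits of -0.19 (29 of 41) and immediate early genes of -0.20 (11 of 15). By the mean of the members none of these 3 lists stood apart, nor did the ribosomal proteins.

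DSN-lite against Total asks what the nuclease treatment removes besides ribosomal RNA. Replication-dependent histone mRNAs were lower for all 49 members (median 3.99-fold lower), with HIST2H3C at -6.22 (48 counts against 3618 [-6.70 to -5.84]). Several short, GC-rich mRNAs were lower by more than the histone median. MIF, a cytokine, was at -6.15 (17 counts against 1304 [-7.06 to -5.59]) and the embryonic globin HBZ at -4.88 [-5.14 to -4.66]. HBA1 was at -3.20 [-3.32 to -3.08] and the complex I subunit NDUFB7 at -3.48 [-4.12 to -3.03]. The response to growth signals, the immediate early genes, was lower in 12 of 14 members (median -0.81), with JUND at -1.88 [-2.17 to -1.68]. The small structured RNAs had a median of -2.29 (5 of 6 lower), with RPPH1 at -2.88 [-2.92 to -2.85], and the snoRNAs of -0.81 (54 of 66 lower).

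The lower genes in DSN-lite were GC-rich. The median ratio went from 0.35 in transcripts below 40% GC to -2.06 in those above 65%, as the plot of GC classes shows. Erythroid and globin genes had a median of -0.18, translation factors of -0.11, ribosomal proteins of -0.08 and OXPHOS subunits of -0.05, each with members on both sides, and the last 3 did not stand apart by the mean of the members. Of 12102 genes, 14 were 4-fold higher and 219 lower as scaled. Relative to the median gene, which lay at 0.54, the counts were 12 and 430. As scaled, the medians of these 4 lists were above 0 (0.36, 0.43, 0.46 and 0.49) and that of the immediate early genes was -0.27. By the mean of the members the small structured RNAs were at -1.45 and the snoRNAs at -1.29.

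**Figure D3:**
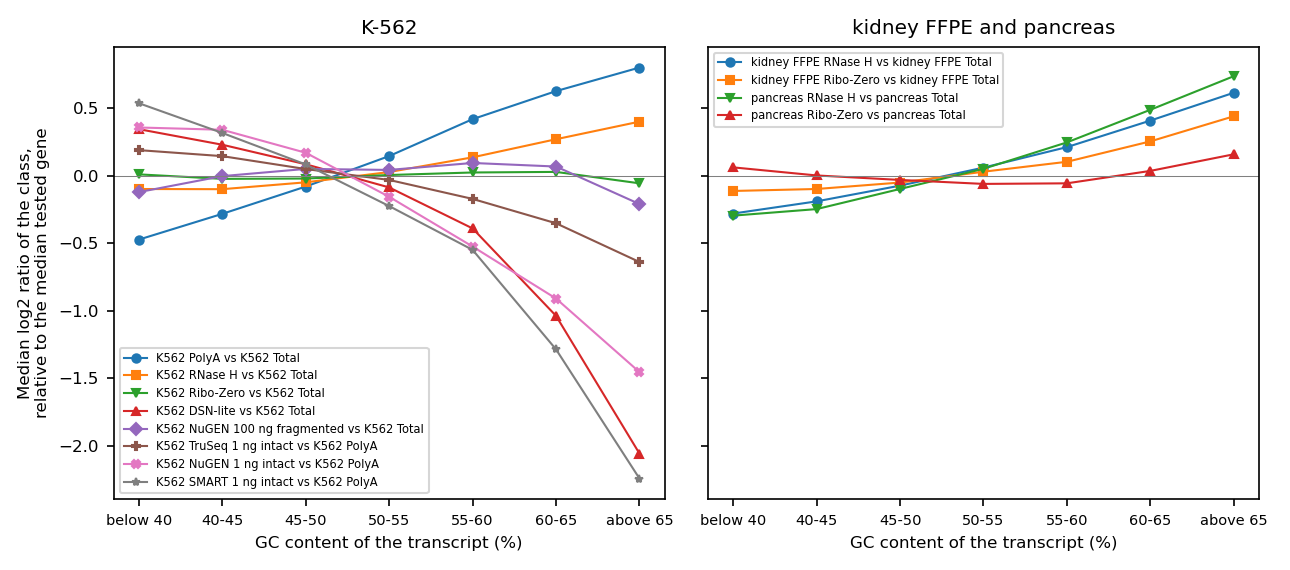
Median log2 ratio, relative to the median tested gene (y axis), of genes grouped by the GC content of their transcript in % (x axis), 1 line per main comparison, K-562 on the left and the tissues on the right. Above 65% GC the median was -2.24 in SMART against PolyA, -2.06 in DSN-lite against Total and 0.80 in PolyA against Total.

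NuGEN 100 ng fragmented against Total tests a cDNA amplification kit at a smaller input. RNAs that end without a poly(A) tail were lower, as in PolyA. Histone mRNAs were lower in 45 of 49 members (median -3.28, 9.71-fold), with HIST1H4C at -6.54 [-7.15 to -6.10]. The 5 small structured RNAs were all lower (median -7.15), with RMRP at -10.47 (57 counts against 50407 [-10.89 to -10.11]), and 62 of 63 snoRNAs and scaRNAs were lower (median -5.87). MTND5 was at -1.69 [-1.72 to -1.66] and SNHG8, a snoRNA host, at -1.69 [-1.91 to -1.49]. The 15 snoRNA host genes had a median of -0.44, which did not stand apart by the mean.

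Several mRNAs were higher in NuGEN 100 ng fragmented, among them SRRM2, a protein of splicing speckles (1.49 [1.46 to 1.53]), the early growth response factor EGR1 (1.59 [1.53 to 1.68]), and both ACTB and GAPDH (1.07 and 1.11). The very long mRNAs (median -0.08) and the immediate early genes (median -0.04) did not stand apart. As scaled, 218 of 12256 genes were 4-fold higher and 154 lower (58.6% higher), but relative to the median gene, at 0.40, the counts were 88 and 215, so the direction of the excess depends on the scaling. The snoRNA median was -2.78 over 24 members in scaled expected counts.

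TruSeq on 1 ng was set against PolyA from 1000 ng, which is not labelled as a library of the same kit. Input and kit can therefore not be told apart, and the same holds for NuGEN 1 ng intact and SMART against PolyA. TruSeq stayed closest to PolyA among the 1 ng libraries, with a rho of 0.952. Immediate early genes were lower in 13 of 16 members (median -0.74), with JUND at -1.52 [-1.68 to -1.38] and JUNB at -1.42 [-1.68 to -1.24]. The snoRNAs and scaRNAs were lower in 14 of 17 (median -1.82). Metazoa_SRP was 24.0-fold lower in TPM (-4.58 [-4.68 to -4.49]), a larger fold than its counts give (932 against 12642). Histone mRNAs were lower in 33 of 46 (median -0.52), with HIST3H2A at -2.59 [-2.88 to -2.35], and OXPHOS subunits in 30 of 41 (median -0.35), with NDUFB2 at -1.53 [-1.68 to -1.38]. Very long mRNAs were higher in 21 of 31 (median 0.20), and 8 of 8 stroma markers were above the median gene (median 0.63).

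C12orf50, a gene of unknown function, was 14.9-fold higher in TruSeq (1394 counts against 71). As scaled, 200 of 12165 genes were 4-fold higher and 84 lower (70.4% higher), and relative to the median gene, at 0.18, 148 and 102 (59.2% higher). In scaled expected counts the histone mRNAs (-0.04), the OXPHOS subunits (-0.13) and the stroma markers (0.53) no longer stood apart, and the snoRNA median was -0.89.

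NuGEN 1 ng intact against PolyA puts the amplification kit at its smallest input beside poly(A) selection. Very long mRNAs were higher in 30 of 31 members (median 1.19, 2.28-fold), with MLL3, a histone methyltransferase, at 1.88 [1.85 to 2.02], and all 6 nuclear long noncoding RNAs were higher (median 1.15), with NEAT1 at 1.19 [1.17 to 1.24]. OXPHOS subunits were lower in 33 of 41 (median -0.79), with NDUFS5 at -2.71 [-2.85 to -2.57], and immediate early genes in 13 of 15 (median -1.21), with JUND at -2.18 [-2.40 to -2.03]. Histone mRNAs had a median of 0.97 with 15 of 49 members 4-fold higher and 4 lower, and the linker histone HIST1H1E was 217-fold higher (13446 counts against 60; 7.76 [7.48 to 8.24]). The medians of all these lists lay on the other side in PolyA against Total. Higher here therefore means higher than in PolyA, and not higher than in Total. Replication-dependent histone mRNAs took 1.33% of TPM in NuGEN 1 ng intact and 0.505% in PolyA, against 4.004% in Total.

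Other short RNAs went both ways in NuGEN 1 ng intact. Metazoa_SRP was at -4.79 [-4.94 to -4.66] and RPS29, a ribosomal protein, at -3.19 [-3.35 to -3.04]. The 19 snoRNAs and scaRNAs had a median of -0.98 with 9 members above the median gene and 10 below, and glycolysis genes a median of -0.56 that did not stand apart. Of 12066 genes, 301 were 4-fold higher and 375 lower, and rho was 0.862. Relative to the median gene 268 were 4-fold higher and 408 lower; of these 174 and 378 had a known GC, and set against genes of like GC there were 194 and 138. In scaled expected counts the immediate early median was -0.59, and over the 7 members with at least 20 counts the snoRNA median was -1.52.

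SMART against PolyA had the largest differences of the main comparisons in K-562: 85 of 11710 genes were 4-fold higher and 1206 lower, and rho was 0.819. Relative to the median gene 122 were higher and 988 lower. Of genes with a known GC these were 79 and 936, which became 194 and 316 when each gene was set against genes of like GC. OXPHOS subunits were higher in 38 of 41 members (median 1.02), with NDUFC1 at 2.36 and COX6C at 1.82. Immediate early genes were lower in 11 of 15 (median -1.38), with DUSP1, a phosphatase, at -3.68 and JUNB at -3.56. The small structured RNAs had a median of -2.45 (-4.65 at a mean TPM of at least 10), with RPPH1 at -5.74. Transcription factor KLF1 of red cells was at -2.51 and BCR, fused to ABL1 in this cell line, at -3.08, while HBA2 was at 3.17 and ACTB at 2.17.

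Lists with members on both sides in SMART were the histone mRNAs (median 0.10, not apart), with HIST1H1E at 5.02 and HIST2H3C at -3.74, and the polyadenylated histone variants (median -0.82, 5 of 7 lower), with the linker histone H1FX at -5.56 and a mean over the members of -1.54. Replication-dependent histone mRNAs took 0.697% of TPM in SMART and 0.505% in PolyA, against 4.004% in Total. Their median close to PolyA therefore does not mean that they were kept. Leukocyte markers were higher in 6 of 8 (median 1.09), with CD52 at 1.80. Translation factors had a median of -0.26, with the elongation factor EEF2 at -2.19. The snoRNA host genes (median -0.89) and the snoRNAs (median -1.24) did not stand apart by the mean, nor did the nuclear long noncoding RNAs (median 1.12, 3 of 5 higher), which turned to -0.51 at a mean TPM of at least 10. Relative to the median gene, at -0.20, 122 genes were 4-fold higher and 988 lower.

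**Figure D4:**
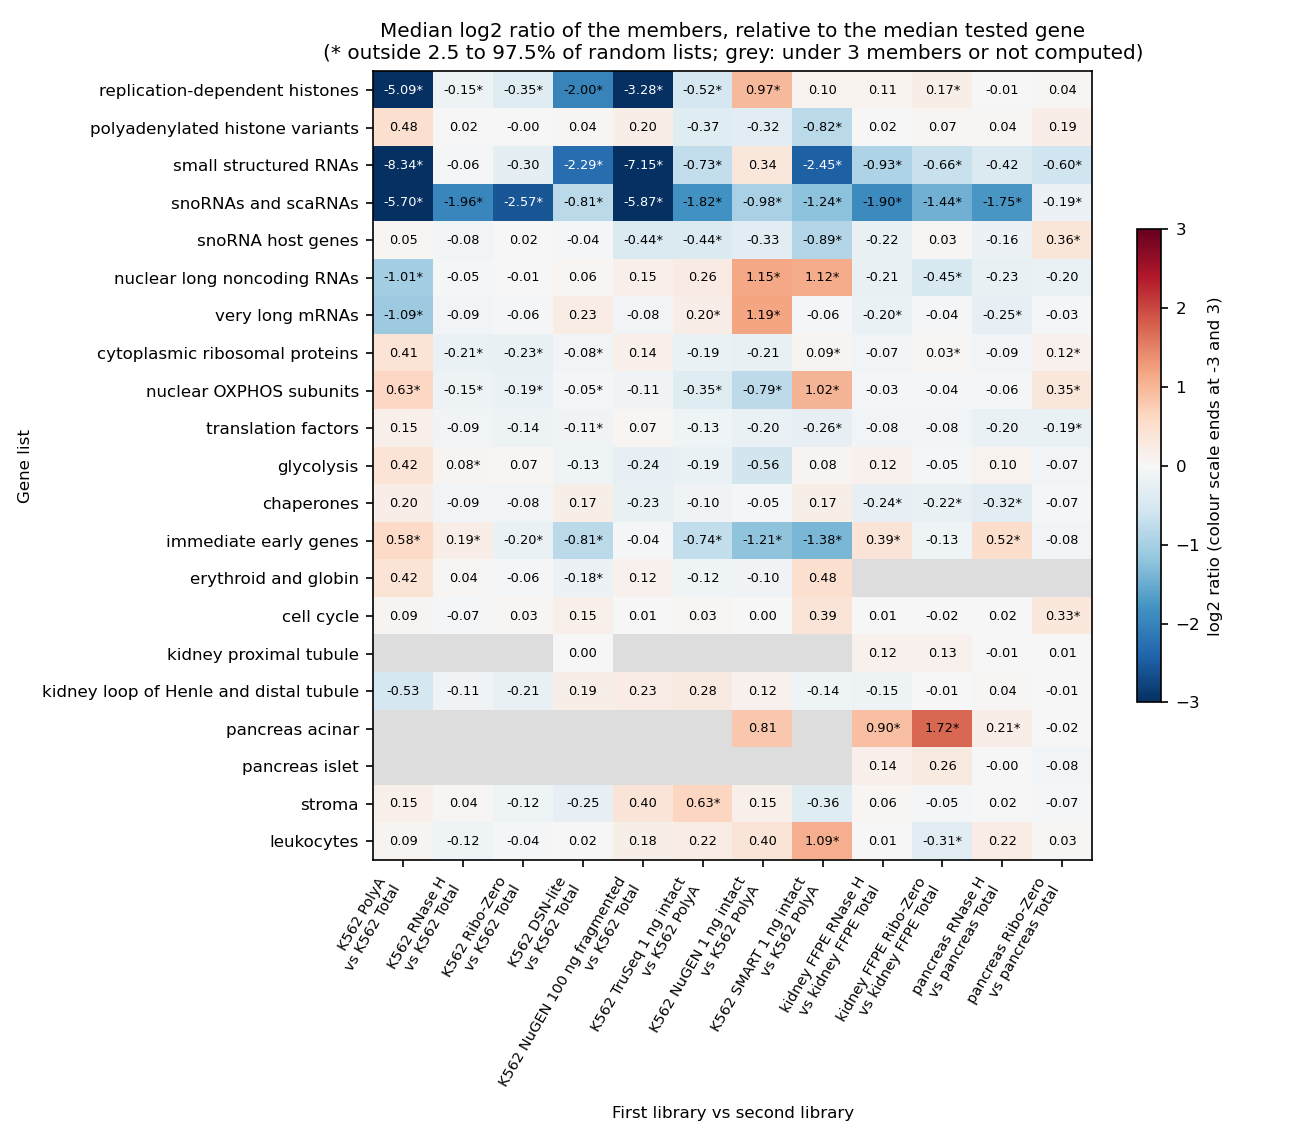
Median log2 ratio of each gene list (rows) in the 12 main comparisons (columns), relative to the median tested gene; colours end at -3 and 3 and a star marks a list outside the central 95% of random lists. Histone mRNAs stood at -5.09 in PolyA and -0.15 in RNase H against Total, and the pancreas acinar list at 1.72 in kidney Ribo-Zero.

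RNase H against Total in FFPE kidney asks how the method serves fixed tissue. Markers of kidney cell types showed no common shift. The lists for proximal tubule (median 0.12), loop of Henle and distal tubule (-0.15), collecting duct (0.22), podocyte (-0.12), stroma (0.06) and endothelium (-0.05) did not stand apart, and SLC12A1, the salt transporter of the loop, was at -0.23 (606 TPM against 775). Immediate early genes were higher in 18 of 19 members (median 0.39), with JUND at 0.77 and the nuclear receptor NR4A1 at 0.75. The snoRNAs and scaRNAs were lower in 69 of 80 (median -1.90). In K-562 this median lay much closer to the median gene in scaled expected counts. The tissues have no counts, so this could not be checked in any tissue pair. Small structured RNAs were lower in 5 of 7 (median -0.93), with the minor spliceosome RNA RNU11 at -2.62 but the telomerase RNA TERC at 1.76.

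As in K-562, MIR3648 was higher (4.67) and RPL37 (-1.15) and RPS27 (-1.03) were lower. Chaperones were lower in 20 of 23 members (median -0.24), with CCT8 at -0.76, and very long mRNAs in 31 of 36 (median -0.20), with AKAP9 at -0.67; neither stood apart by the mean. The pancreas acinar list, digestive enzymes that are not kidney genes, was higher in 23 of 26 members (median 0.90, 1.86-fold), with the lipase cofactor CLPS at 1.97 (17.4 TPM against 4.14). Of 16506 genes, 32 were 4-fold higher and 73 lower as scaled, and 40 and 64 relative to the median gene at -0.13.

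Ribo-Zero against Total in FFPE kidney puts the same question to the capture kit. The acinar list was again higher, in 25 of 26 members (median 1.72, 3.30-fold), with CLPS at 3.34 (43.8 TPM against 4.14), the elastase CELA3B at 2.63 and CPA1, a carboxypeptidase, at 2.31. MTND5 was 9.91-fold lower (-3.31), HSPB1 at -1.56, and the immediate early genes ZFP36 and IER3 at -1.50 and -1.20. The snoRNAs and scaRNAs had a median of -1.44 with 34 of 82 members 4-fold lower and 6 higher, and the snoRNA host SNHG1 was at -1.99.

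Kidney cell types again did not stand apart in Ribo-Zero: proximal tubule 0.13, loop of Henle and distal tubule -0.01, collecting duct -0.06, podocyte -0.14, stroma -0.05 and endothelium 0.01. Leukocyte markers had a median of -0.31 (12 of 17 lower), with CD74, a chaperone of antigen presentation, at -0.56. Chaperones had a median of -0.22, nuclear long noncoding RNAs of -0.45 and small structured RNAs of -0.66. By the mean of the members none of these 4 lists stood apart. Histone mRNAs were at 0.17 (37 of 58 higher) and at -0.0475 as scaled. As scaled, 36 of 16398 genes were 4-fold higher and 87 lower (29.3% higher), and relative to the median gene, at -0.22, 50 and 71 (41.3% higher).

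RNase H against Total in pancreas repeats the comparison in a second tissue. Acinar enzymes were close to the median gene as a list (median 0.21, 16 of 29 higher), with the chymotrypsinogen CTRB1 at 1.23 and the phospholipase PLA2G1B at -0.75. Islet (-0.00), duct (0.10), stroma (0.02) and endothelium (0.16) markers did not stand apart, and GCG, the precursor of glucagon, was at -0.77. Immediate early genes were higher in 12 of 15 members (median 0.52), with JUND at 1.13 and JUNB at 0.96. The snoRNAs and scaRNAs were lower in 26 of 36 (median -1.75), and SNHG1 was at -3.29. Some snoRNAs had a TPM of 0 on either side, such as SNORA10 (0 against 124 TPM) and SNORA76 (27.3 against 0).

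MIR3648 was higher here too (4.53), and RPL37 (-1.07) and RPS27 (117 TPM against 306) were lower. RPL37 lay between -1.15 and -1.07 in all 3 RNAs. Chaperones were lower in 17 of 23 members (median -0.32), with the endoplasmic reticulum chaperone HSP90B1 at -0.61, and very long mRNAs in 23 of 32 (median -0.25). Neither list stood apart by the mean. As scaled, 17 of 12521 genes were 4-fold higher and 37 lower (31.5% higher), and relative to the median gene, at -0.39, 32 and 23 (58.2% higher); as scaled the acinar median was -0.18, so its direction rests on the scaling.

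Ribo-Zero against Total in pancreas completes the set. MTND5 was at -3.10 and HSPB1 at -2.10, so both were lower after Ribo-Zero in all 3 RNAs, as was SRRM2 (-0.70 in K-562, -0.58 in kidney and -0.78 in pancreas). OXPHOS subunits were higher in 30 of 41 members (median 0.35), with NDUFS5 2.14-fold higher, ribosomal proteins in 46 of 76 (median 0.12), with RPL35 at 1.05, and snoRNA host genes in 10 of 14 (median 0.36), with SNHG12 at 2.83 but SNHG1 at -3.04. Acinar (-0.02), islet (-0.08) and duct (-0.10) lists did not stand apart, and SST, the hormone somatostatin, was at -1.16.

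The snoRNAs and scaRNAs of this pair split into 11 members 4-fold higher and 13 lower (median -0.19). Translation factors (median -0.19) and small structured RNAs (median -0.60) did not stand apart by the mean, and the cell cycle list (median 0.33) turned to -0.04 over the 3 members at a mean TPM of at least 10. Of 12756 genes, 29 were 4-fold higher and 43 lower.

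Between the depletion methods, Ribo-Zero held less of the immediate early genes than RNase H in each RNA: 13 of 15 members were lower in K-562 (median -0.45), 17 of 19 in kidney (-0.40) and 12 of 15 in pancreas (-0.64). The pancreas call was lost at a mean TPM of at least 10 (-0.33, 7 members). Across all genes at that level, rho between GC content and the ratio was -0.47 in K-562, -0.35 in kidney and -0.70 in pancreas. The immediate early genes were not set against genes of like GC, so their shift is not told apart from GC. In K-562 RMRP was at -2.07 [-2.12 to -2.03], MTND5 at -2.12 [-2.17 to -2.08] and HSPB1 at -1.60 [-1.77 to -1.46], while RPS27 was at 1.13 [1.02 to 1.24]. RPS27 was higher in Ribo-Zero in kidney (1.56) and pancreas (1.62) as well. The acinar list was higher in kidney Ribo-Zero (25 of 26, median 0.96) and at -0.24 in pancreas (0.0489 as scaled). Genes beyond 4-fold numbered 56 of 11965 in K-562, 100 of 16272 in kidney and 49 of 12422 in pancreas, where 57.1% were higher as scaled and 37.9% relative to the median gene at 0.29.

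Both versions of RNase H differed least of all pairs: 29 of 12018 genes were beyond 4-fold, rho was 0.994 and the SD of the log2 ratios 0.231. The labels do not explain "NS". Small structured RNAs were at a median of 0.25, with 7SK at 0.25 [0.22 to 0.29], a call that was lost in scaled expected counts (0.02) and reversed at a mean TPM of at least 10 (-0.00353) and at 20 or more counts (-0.0403). Every other list median of this pair was closer to the median gene, the next being the snoRNAs at -0.06. PCR before the nuclease in DSN-lite gave 30 of 11933 genes beyond 4-fold. Ribosomal proteins were higher in 71 of 76 members (median 0.21, but -0.0916 as scaled), histone mRNAs in 41 of 50 (median 0.39, and 0.0878 as scaled), and Metazoa_SRP was 9.27-fold higher (3.21 [3.18 to 3.25]), with the fetal globin HBG1 at 1.25 [1.22 to 1.28]. The split of the 30 genes was 13.3% higher as scaled and 26.7% relative to the median gene at -0.31.

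At 1 ng, NuGEN fragmented stood apart from both other NuGEN libraries, which agreed best with each other (rho 0.951) although they differ in input and fragmentation. These pairs therefore do not rank fragmentation against input, and NuGEN 1 ng fragmented also has the fewest counts of the 3. Against NuGEN 1 ng intact, the fragmented library had 693 of 12110 genes beyond 4-fold and a rho of 0.884. Histone mRNAs were higher in 36 of 48 members (median 0.61), chaperones lower in 21 of 23 (median -0.64), with HSPD1 at -1.13 [-1.19 to -1.08], and HBA1 was at 2.26 [2.19 to 2.34]. Polyadenylated histone variants had a median of 0.66, which did not stand apart by the mean. Against NuGEN 100 ng fragmented, 291 of 12169 genes were beyond 4-fold and rho was 0.931. Histone mRNAs were higher in 40 of 47 (median 0.50), chaperones lower in 17 of 23 (median -0.21), and the snoRNA host SNHG3 was at 1.96 [1.86 to 2.09]. The small structured RNAs (4 members) were higher in both pairs, with medians of 1.47 and 0.82, the latter not apart in scaled expected counts.

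Detection was similar across K-562 libraries, from 11166 genes at a TPM of 1 or more in SMART to 12550 in TruSeq, and it was 16153 to 16579 genes in kidney and 12116 to 12855 in pancreas. At equal depth, 12061 (NuGEN 1 ng fragmented) to 13426 (TruSeq) genes had at least 5 counts. The most abundant isoform was compared in genes with more than 1 isoform and a TPM of at least 5 in both libraries. It was the same as in the reference for 90.3% in RNase H, 88.8% in Ribo-Zero, 88.2% in PolyA and 82.6% in DSN-lite. It was the same for 72.2% in NuGEN 100 ng fragmented against Total, and for 75.3%, 72.8% and 79.6% in TruSeq, NuGEN 1 ng intact and SMART against PolyA. In the tissues RNase H and Ribo-Zero gave 78.5% and 77.6% (kidney) and 83.6% and 81.7% (pancreas). By length, transcripts below 500 nt had a median of -4.49 in PolyA and -4.08 in NuGEN 100 ng fragmented, and those above 8000 nt of -0.70 in PolyA and 0.67 in NuGEN 1 ng intact. Of genes classed by their level in PolyA, the 136 at 1000 TPM or more lay slightly below the median gene against Total. Their medians were -0.16 in DSN-lite, -0.13 in RNase H and -0.21 in Ribo-Zero. This class misses RNAs that are abundant in Total but not in PolyA. RMRP is such an RNA, with 8.26% of TPM in Total and 0.642% in Ribo-Zero. In SMART against PolyA, the 122 genes at 1000 TPM or more in Total had a median of -0.20, and those from 100 to 1000 TPM one of 0.28.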

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

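Ribo-Zero against Total gave 3 lists that lay below the median gene in K-562 and above it in a tissue. Replication-dependent histones were at -0.35 in K-562 and 0.17 in kidney. Cytoplasmic ribosomal proteins were at -0.23 in K-562, 0.0323 in kidney and 0.12 in pancreas, and nuclear OXPHOS subunits at -0.19 in K-562 and 0.35 in pancreas. They are listed here because the groups move opposite ways, and the differences themselves were not tested, with 1 library per group. As scaled, the kidney medians were -0.0475 for histones and -0.185 for ribosomal proteins, so the directions in kidney depend on centring, while in pancreas ribosomal proteins (0.0340) and OXPHOS subunits (0.257) stayed above 0.

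The test over all lists was written down before its result was seen, and the 3 tests of single lists after; the pattern had been seen before them. GC content and length of the members may play a part for the histones: 75.9% of the gap between kidney and K-562 was left after setting members against like genes (44.6 to 98.1), which leaves the matter open. For ribosomal proteins 91.0% of the gap between pancreas and K-562 was left (64.3 to 107), and for OXPHOS subunits 85.0% (60.1 to 105). Length and GC here are those of the longest annotated transcript, such as 7686 nt for RPL37. The transcripts in these RNAs may be others, so these values do not exclude GC and length as the cause. The median of ribosomal proteins went from 0.12 to 0.0911 in pancreas, and in kidney from 0.0323 to -0.0120, so its place above the median gene in kidney was not kept. Over all lists, 1 of the 3 kept opposite signs beyond 0.1, too few to decide. Damage to the tissue RNA could also differ from that of K-562, but with 91.0% and 85.0% of the gaps unexplained this was not tested, and neither was any biological explanation.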

How the results depend on the processing

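No paired analysis was possible within an RNA because each group holds 1 library. Across the 3 RNAs, a test of RNase H and Ribo-Zero against Total with the RNA as a block was not run, and only directions were compared. In brackets stand the values of the setting used in the text.

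A pseudocount of 0.1 TPM in place of 1 moved the number of genes beyond 4-fold, upward in each case, because ratios of weak genes are damped less. PolyA against Total gave 413 (228), DSN-lite against Total 403 (233) and NuGEN 100 ng fragmented against Total 601 (372). TruSeq 1 ng intact against PolyA had 673 (284), NuGEN 1 ng intact against PolyA 1224 (676) and kidney RNase H against Total 259 (105). Kidney Ribo-Zero against Total showed 309 (123), pancreas RNase H against Total 176 (54) and pancreas Ribo-Zero against Total 162 (72). Ribo-Zero against RNase H came to 86 (56), DSN-lite PCR against DSN-lite 55 (30) and NuGEN 1 ng fragmented against NuGEN 1 ng intact 1307 (693). NuGEN 1 ng fragmented against NuGEN 100 ng fragmented stood at 836 (291), kidney Ribo-Zero against RNase H 257 (100) and pancreas Ribo-Zero against RNase H 144 (49).

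A pseudocount of 5 TPM damped weak genes more and lowered the number beyond 4-fold in all pairs. RNase H against Total had 29 (58), Ribo-Zero against Total 45 (78) and DSN-lite against Total 94 (233). NuGEN 100 ng fragmented against Total showed 220 (372), TruSeq 1 ng intact against PolyA 51 (284) and NuGEN 1 ng intact against PolyA 234 (676). SMART 1 ng intact against PolyA came to 568 (1291), kidney RNase H against Total 44 (105) and kidney Ribo-Zero against Total 60 (123). Pancreas RNase H against Total stood at 23 (54), pancreas Ribo-Zero against Total 39 (72) and Ribo-Zero against RNase H 15 (56). RNase H NS against RNase H reached 3 (29), DSN-lite PCR against DSN-lite 19 (30) and NuGEN 1 ng fragmented against NuGEN 1 ng intact 109 (693). NuGEN 1 ng fragmented against NuGEN 100 ng fragmented held 22 (291), kidney Ribo-Zero against RNase H 35 (100) and pancreas Ribo-Zero against RNase H 26 (49). PolyA against Total returned 130 (228).

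Keeping only genes at a mean TPM of at least 10 removes weak genes and so lowers most counts. DSN-lite against Total showed 136 (233), TruSeq 1 ng intact against PolyA 62 (284) and NuGEN 1 ng intact against PolyA 415 (676). SMART 1 ng intact against PolyA came to 854 (1291), kidney RNase H against Total 40 (105) and kidney Ribo-Zero against Total 60 (123). Pancreas RNase H against Total stood at 27 (54), Ribo-Zero against RNase H 18 (56) and RNase H NS against RNase H 3 (29). DSN-lite PCR against DSN-lite reached 13 (30), NuGEN 1 ng fragmented against NuGEN 1 ng intact 258 (693) and NuGEN 1 ng fragmented against NuGEN 100 ng fragmented 67 (291). Kidney Ribo-Zero against RNase H held 28 (100), pancreas Ribo-Zero against RNase H 30 (49) and RNase H against Total 31 (58). Ribo-Zero against Total returned 48 (78).

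Keeping genes with at least 20 expected counts moved these counts; this could be run only where counts are given. RNase H NS against RNase H came to 0 (29), DSN-lite PCR against DSN-lite 4 (30) and RNase H against Total 17 (58). Ribo-Zero against Total stood at 26 (78) and Ribo-Zero against RNase H 17 (56).

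Using expected counts scaled to the library total in place of TPM leaves length out of the scaling. TruSeq 1 ng intact against PolyA stood at 180 (284), Ribo-Zero against RNase H 16 (56) and RNase H NS against RNase H 0 (29). DSN-lite PCR against DSN-lite reached 3 (30), RNase H against Total 9 (58) and Ribo-Zero against Total 15 (78). DSN-lite against Total held 364 (233) and NuGEN 100 ng fragmented against Total 209 (372).

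Rescaling TPM without the small structured and mitochondrial RNAs moved these counts, and the cause was not tested. Ribo-Zero against RNase H reached 26 (56), RNase H NS against RNase H 13 (29) and DSN-lite PCR against DSN-lite 10 (30). Kidney Ribo-Zero against RNase H held 297 (100), RNase H against Total 20 (58) and Ribo-Zero against Total 30 (78). NuGEN 100 ng fragmented against Total returned 242 (372), kidney RNase H against Total 241 (105) and kidney Ribo-Zero against Total 313 (123).

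Keeping clusters that share a symbol apart moved these counts, and the cause was not tested. Kidney RNase H against Total held 164 (105), DSN-lite PCR against DSN-lite 50 (30) and kidney Ribo-Zero against RNase H 168 (100).

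Centring on the median gene moved 1 count by more than 1.5 times. DSN-lite against Total returned 442 (233).

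Rank agreement across genes moved at a mean TPM of at least 10 in all 19 pairs, which narrows the range of expression. Kidney RNase H against Total yielded 0.885 (0.951), kidney Ribo-Zero against Total 0.888 (0.95) and pancreas RNase H against Total 0.788 (0.916). Pancreas Ribo-Zero against Total gave 0.851 (0.939), Ribo-Zero against RNase H 0.963 (0.983) and RNase H NS against RNase H 0.992 (0.994). DSN-lite PCR against DSN-lite had 0.986 (0.989), NuGEN 1 ng fragmented against NuGEN 1 ng intact 0.807 (0.884) and NuGEN 1 ng fragmented against NuGEN 100 ng fragmented 0.89 (0.931). Kidney Ribo-Zero against RNase H showed 0.907 (0.955), pancreas Ribo-Zero against RNase H 0.782 (0.912) and PolyA against Total 0.817 (0.909). RNase H against Total came to 0.964 (0.981), Ribo-Zero against Total 0.955 (0.977) and DSN-lite against Total 0.878 (0.931). NuGEN 100 ng fragmented against Total stood at 0.802 (0.904), TruSeq 1 ng intact against PolyA 0.919 (0.952) and NuGEN 1 ng intact against PolyA 0.732 (0.862). SMART 1 ng intact against PolyA reached 0.68 (0.819).

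The percentage of genes with the same dominant isoform was higher in all 19 pairs among genes at a TPM of at least 20. Kidney Ribo-Zero against Total gave 80.9 (77.6), pancreas RNase H against Total 90.7 (83.6) and pancreas Ribo-Zero against Total 89.95 (81.7). Ribo-Zero against RNase H had 92.4 (89.97), RNase H NS against RNase H 95.2 (92.4) and DSN-lite PCR against DSN-lite 92.9 (89.94). NuGEN 1 ng fragmented against NuGEN 1 ng intact showed 74.1 (69.6), NuGEN 1 ng fragmented against NuGEN 100 ng fragmented 78.9 (74.7) and kidney Ribo-Zero against RNase H 82 (78.9). Pancreas Ribo-Zero against RNase H came to 90.2 (82.8), PolyA against Total 91.1 (88.2) and RNase H against Total 93 (90.3). Ribo-Zero against Total stood at 91.4 (88.8), DSN-lite against Total 85.9 (82.6) and NuGEN 100 ng fragmented against Total 74.6 (72.2). TruSeq 1 ng intact against PolyA reached 81.7 (75.3), NuGEN 1 ng intact against PolyA 76.4 (72.8) and SMART 1 ng intact against PolyA 85.5 (79.6). Kidney RNase H against Total held 82.1 (78.5).

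Counting genes at a TPM of at least 5 in place of 1 moved the number detected by more than 1.5 times in 3 libraries, all in pancreas. Pancreas Ribo-Zero had 7422 (12657), pancreas Total 7745 (12855) and pancreas RNase H 6371 (12116).

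In expected counts scaled to the library total the following list medians reversed, and the cause was not tested. Replication-dependent histones in RNase H against Total stood at 0.0141 (-0.15). The snoRNAs and scaRNAs in RNase H NS against RNase H had a median of 0.0153 (-0.06).

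With TPM as scaled and not centred, these list medians changed sign, which follows from adding the median shift of the pair. Cytoplasmic ribosomal proteins in DSN-lite against Total came to 0.46 (-0.08). Nuclear OXPHOS subunits in DSN-lite against Total lay at 0.49 (-0.05). Translation factors in DSN-lite against Total turned to 0.43 (-0.11). Erythroid and globin genes in DSN-lite against Total were at 0.36 (-0.18). Replication-dependent histones in kidney Ribo-Zero against Total stood at -0.0475 (0.17). Pancreas acinar genes in pancreas RNase H against Total had a median of -0.18 (0.21). Pancreas acinar genes in pancreas Ribo-Zero against RNase H came to 0.0489 (-0.24). Cytoplasmic ribosomal proteins in DSN-lite PCR against DSN-lite lay at -0.0916 (0.21).

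At a mean TPM of at least 10 fewer members remain, and these list medians reversed. Nuclear long noncoding RNAs in SMART 1 ng intact against PolyA turned to -0.51 (1.12). Cell cycle genes in pancreas Ribo-Zero against Total were at -0.0441 (0.33). Small structured RNAs in RNase H NS against RNase H stood at -0.00353 (0.25).

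With at least 20 expected counts per member, the reversed medians were these. Small structured RNAs in RNase H NS against RNase H had a median of -0.0403 (0.25).

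Of 467 list results under alternatives other than TPM as scaled, 416 kept their call, 39 lost it, 6 gained one and 6 reversed. TPM as scaled is left out of that count because the rank among random lists cannot change there; of its 117 results 8 changed sign with the shift of the median gene. The 306 results for named genes cover 120 ratios and not all named genes. Of the 306, none reversed and 51 moved by more than their counting interval or a limit of 0.25. The limit was chosen after the results were seen. Of the 51, 20 moved to larger and 31 to smaller values. Some other named genes did change sign with TPM as scaled. In pancreas RNase H against Total, ACTB went from 0.21 to -0.18 and GAPDH from 0.19 to -0.19. Thinning to equal counts moved none of the counts in the 12 pairs where it could be run, and neither did a second seed in 11 libraries. Depth differed by much only in the pairs with NuGEN 1 ng fragmented (6010007 expected counts). The other libraries with counts held 10007074 to 10122517, so thinning could hardly move their pairs. Leaving out the filter cannot add genes beyond 4-fold, since a mean TPM below 1 with the added 1 keeps the ratio below 2, and rank agreement cannot depend on the pseudocount, so these alternatives say nothing about robustness. SMART and the tissues have no counts, so the alternatives that need counts, and any limit set by depth, are unknown there.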

Other observations

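The test of carry-over by method was written down before its result was seen and the other 5 tests here after; each pattern had been seen before its tests. The other values here were chosen after the results were seen, and nothing was tested on them.

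Transcripts of pancreas acinar cells appeared in all 3 kidney libraries. Their summed TPM was 631 in RNase H, 1173 in Ribo-Zero and 377 in Total, against at most 9.96 in a K-562 library. That is 0.179%, 0.351% and 0.102% of the level in the pancreas library of the same method. In kidney Ribo-Zero against Total the list stood at 1.72.

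A property of Ribo-Zero that raises these transcripts is not borne out, since the list stood at -0.0154 in the pancreas pair (quartiles -0.19 to 0.13). Carry-over from the pancreas library of the same method might show in the ratios of single members. There rho was -0.31 (-0.61 to 0.08) over 26 members, which speaks against it for these genes. Pancreas RNA present in the kidney RNA before the libraries were made, and recovered as in the pancreas RNA, would give its members the same ratio in both tissues; the ratios in kidney were higher by a median of 1.72 (1.53 to 2.05), so this alone does not account for the difference between the libraries. Pancreas RNA recovered otherwise because it was less damaged than the kidney RNA, or carry-over that does not follow the method, was not tested. No biological explanation was tested.

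DSN-lite against Total had 430 genes at least 4-fold below the median gene. GC content likely explains most of them. Set against genes of like GC, 21.9% (87 of 397 with known GC, binomial interval 18.1 to 26.2) stayed 4-fold below. The median GC of the 397 was 65.1% against 48.1% in all genes. Abundance in PolyA does not, as 96.3% (binomial interval 94.0 to 97.7) stayed below genes of like abundance there. That level understates RNAs without a poly(A) tail, such as histone mRNAs. The lack of PCR before the nuclease is not the reason, because with PCR these genes stood only 0.41 higher (quartiles 0.23 to 0.59). Of these genes 309 passed the filter. Why GC-rich sequence is lost cannot be told from these libraries, and no biological explanation was tested.

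Leukaemia and red cell genes differed unevenly between the 1 ng libraries and PolyA from 1000 ng. HBA1, an alpha globin, was at -2.26 [-2.34 to -2.19] in NuGEN 1 ng intact against PolyA, while the gamma globin HBG1 was at 1.17 [1.16 to 1.19]. BCR, the partner of ABL1 in the fusion of this leukaemia, was at -1.44 in NuGEN 1 ng intact, -3.08 in SMART and -0.29 in TruSeq against PolyA. ABL1 itself was at -1.70 in SMART and -0.16 in TruSeq. Kit and input cannot be told apart here, and these genes were not set against genes of like GC. HBA1 has 64.5% GC and HBG1 47.0%. Across genes, rho between GC and the ratio was -0.48 in NuGEN 1 ng intact, -0.47 in SMART and -0.46 in TruSeq. The GC-rich HBA2 (64.4%) was nevertheless at 3.17 in SMART.

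GC-rich transcripts were higher after RNase H in all 3 RNAs. Transcripts above 65% GC had a median of 0.40 in RNase H against Total in K-562, 0.62 in kidney and 0.74 in pancreas. In Ribo-Zero the same class was at -0.06 in K-562, 0.44 in kidney and 0.16 in pancreas. For RNase H against Total, rho between GC content and the ratio was 0.54 in K-562, 0.67 in kidney and 0.72 in pancreas. It was taken across genes at a mean TPM of at least 10. The immediate early genes, higher in the same pairs, were not set against genes of like GC.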
